A study of Escherichia coli str. K-12 substr. MG1655 with 60 samples.

How the data were processed

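Total RNA from chemostat cultures of Escherichia coli K-12 MG1655 was converted to labelled cDNA and hybridised to 60 Affymetrix arrays, per the labels' protocols, which also state 1 g/l glucose, a working volume of 100 ml and withdrawal within 3 min. The deposited values were log2 probe set summaries of 8465 probe sets with 2 decimals. RMA and limma are named in the submitters' processing notes, with no version given in the sources used here, and nor were the background step or probe set filter. RMA makes the distributions of arrays alike, and lower quartiles were 6.00 to 6.01 and medians 7.78 on all arrays, so a shift of all transcripts at once would not be seen. The authors' deposited tables also give, for 10 comparisons, a linear ratio and a p-value for 5076 to 5109 probe sets each; the ratios equal the ratios of group means of the value table to within 0.036. The criterion by which these probe sets were chosen is not given in the sources used here.

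The labels assign the arrays to 20 groups of 3. No pair of arrays of a group held equal values, and the SD of the difference between 2 arrays of a group ran from 0.136 to 0.462. The 65 Affymetrix control probe sets were left out, leaving 8400. Gene names came from the authors' deposited tables and, through the Entrez number, from the RefSeq gene table of assembly ASM584v2, which was used for names and locus tags only: 4323 probe sets had 1 gene (4293 named through the table, 30 with the file's name), 32 had several and are not named, 738 had no gene name, and 3307 were in none of the comparison tables and are unnamed here. The array files name no genome build, so no coordinates are given. For each gene the probe set with the highest mean was used, which gave 4145 genes without rRNA and tRNA.

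One linear model with a coefficient per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 40 residual degrees of freedom, two-sided). All groups thus share an estimate of the spread, though their own spreads differed. The median SD over probe sets ran from 0.075 to 0.178 between groups. Intervals may be too narrow and p-values too small for comparisons of widely spread groups, and the reverse for the others. Adjusted p-values are Benjamini-Hochberg over the 8400 probe sets, called under 0.05. Contrasts were the 10 comparisons, the averages over all 8 field conditions, by waveform and by time, an F-test of whether the field effect differs between conditions and an F-test between the 8 sham groups. The 33 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 33 lists for H2O2 and over 264 pairs for the field comparisons. Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

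Genes named were, in a comparison with 30 or more called genes, the 15 highest and 15 lowest log2 fold changes among called genes whose 3 arrays of a group all lay beyond those of the other; in other comparisons the called genes and the 3 smallest p in each direction; the 4 members with the largest absolute change of each list called with the preset correlation; and the response genes katG, ahpC, dps, grxA, soxS, recA, sulA, dnaK, groL, rpoS, fepA and sufA. Genes of the sham, water and unexposed contrasts were named after their values were seen. The text gives a selection.

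The code was tested on simulated data before use, with 200 of 8400 probe sets changed at once, 50 at each of 4 folds (1.5, 2, 3 and 4). In the simulated H2O2 comparison 70% of the 1.5-fold and 100% of the 2-fold changes were recovered. In the 8 simulated field comparisons these shares were 72% to 84% and 86% to 100%, and over the simulated comparisons 2.63% to 7.80% of calls were false. The simulated noise was independent between probe sets, so the share of false calls need not hold for real arrays, whose genes may vary together. Same-numbered arrays of the compared groups were checked for shared deviations: 15 of 30 pairs correlated above 0.1, and the numbers were not taken as pairs. In the chamber comparison all 3 pairs lay between 0.101 and 0.123, but the best correlation with another number was higher for each (0.136 to 0.256). There the blocked model also called 0 probe sets. Alternatives were a replicate block, only the 6 arrays of a comparison, probe sets above the median level, median centring, quantile normalization, array weights, trended robust eBayes, a threshold of at least 2-fold, the authors' p-values, and leaving out each replicate. Chosen after seeing the data were a covariate for the sugar uptake list, leaving out the 4 arrays with a mean over 3 MADs below the median, gene-by-gene array weights, and contrasts between sham times and series and of the response control with the unexposed cultures.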

Results

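The transcriptome of Escherichia coli K-12 MG1655, a laboratory strain with a fully annotated genome, was measured on 60 Affymetrix arrays. The cells grew aerobically in glucose-limited chemostats, in which fresh medium sets a constant growth rate, at a dilution rate of 0.4 per h. Extremely low-frequency magnetic fields were applied as a continuous sinusoidal field, an intermittent sinusoidal field or an intermittent power line signal, the intermittent ones with 2 min on and 4 min off. The continuous sinusoidal and the power line series were sampled after 8 min, 2.5 h and 15 h, and the intermittent sinusoidal series after 2.5 h and 15 h. Each of these 8 conditions had 3 field and 3 sham arrays. Unexposed cultures of the left and the right exposure chamber (3 arrays each) served as a negative control, and cultures given 1 mM H2O2 or water for 10 min (3 arrays each) as a response control. The deposited values were log2 probe set levels with a median of 7.78 on every array, and 8400 probe sets were tested, of which 4145 were taken as the probe set of a named gene. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these arrays, which may be partly technical. The number of arrays, 3 per group, limits the precision.

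The response control asked what a known oxidant did to these cultures. Relative to water, H2O2 raised the genes of the SOS response to DNA damage and lowered those of nitrogen assimilation and pyrimidine synthesis. Of the peroxide defence genes of the OxyR regulon 11 of 20 rose, a list whose call was lost with an estimated correlation (adjusted p = 0.201). The small RNA oxyS (b4458), which is made when the peroxide sensor OxyR is oxidised, rose 13.3-fold, from 10.66 ± 0.38 to 14.39 ± 0.10 (mean log2 level ± SD, n = 3 each; adjusted p = 1.18e-15, limma). The ammonium regulator gene glnK (b0450) fell by 3.74 on the log2 scale (SE 0.39), from 12.98 ± 0.26 to 9.23 ± 0.56. In all, 1755 of the 8400 probe sets changed, 942 upward and 813 downward, and 1318 of the 4145 genes. A change of at least 2-fold was seen for 194 probe sets, 82 of them higher and 112 lower. With only the 6 arrays of this comparison in the model, 822 probe sets were called.

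All 27 measured genes of the SOS response, which LexA controls, rose, with a median log2 fold change of 1.60 (27 also when adjusted over the list alone). The recombination regulator gene recX (b2698) rose 10.7-fold, the repair gene recN (b2616) 8.71-fold and the mutagenic polymerase genes umuD and umuC 8.73-fold and 7.67-fold. The division inhibitor gene sulA (b0958) rose 5.58-fold, the excision repair gene uvrA 4.43-fold, the polymerase gene dinB 4.28-fold, dinD 7.26-fold and the recombinase gene recA (b2699) 2.96-fold. The list was called by camera with the preset correlation (adjusted p = 2.94e-48) and with an estimated correlation (adjusted p = 1.51e-11). The mean level of the list was 11.99 ± 0.01 on the H2O2 arrays, 10.21 ± 0.02 on the water arrays (n = 3 each) and 10.06 ± 0.02 on the unexposed ones (n = 6).

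Of the 20 measured genes of the OxyR regulon, 11 rose, 0 fell and 9 were not called (12 rose when adjusted over the list alone). Catalase-peroxidase katG (b3942) rose 4.58-fold (log2 SE 0.09), glutaredoxin grxA 2.87-fold, the DNA-binding ferritin dps 2.20-fold and the peroxidase gene ahpC 1.47-fold. The katG level was 13.92 ± 0.15 with H2O2, 11.72 ± 0.18 with water and 12.35 ± 0.09 on the 6 unexposed arrays. Over the unexposed level katG rose by 1.56 on the log2 scale (SE 0.08), less than over water. Of the 17 genes of the SoxRS regulon, which responds to superoxide and redox-cycling agents, 12 rose and 0 fell (13 rose when adjusted over the list alone). They included ydbK (3.30-fold), the flavodoxin reductase gene fpr (2.47-fold), the fumarase gene fumC (2.32-fold) and the endonuclease gene nfo (2.20-fold), while soxS rose 1.59-fold, a rise that was not called without H2O2 replicate 2 (log2 fold change 0.54). Iron-sulphur cluster assembly had 12 of 14 genes up and 0 down (13 up over the list alone), such as sufE (2.00-fold) and sufD (1.67-fold), whereas sufA stood at a log2 fold change of 0.23 (SE 0.19; adjusted p = 0.470). The SoxRS list kept its call with an estimated correlation (adjusted p = 0.0258); the OxyR list (adjusted p = 0.201) and the iron-sulphur list (adjusted p = 0.393) did not.

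Genes of nitrogen assimilation fell, 11 of 14 in the NtrC list and 0 rose (12 fell when adjusted over the list alone), with a median log2 fold change of -1.05 and adjusted p = 0.00125 with an estimated correlation. The log2 fold change was -3.47 for the regulator gene nac, -2.77 for the ammonium channel gene amtB and -2.14 for glnG. On the 6 unexposed arrays glnK stood at 10.07 ± 0.78, between its levels with H2O2 and with water. All 9 measured genes of pyrimidine synthesis fell (9 over the list alone; median -1.68; adjusted p = 0.0202 with an estimated correlation), among them pyrD (-2.11), pyrB (-1.86) and pyrI (-1.74). In the arginine list, which shares the carbamoyl phosphate synthase genes carA and carB with it, 9 of 12 genes fell and 0 rose (9 fell over the list alone). There carB stood at -2.04, argH at -1.92 and carA at -1.68, and the call of the list was lost with an estimated correlation (adjusted p = 0.382). Against the unexposed cultures, 3 arginine genes were higher and 3 lower with H2O2 (median -0.01), and 10 of 12 were higher with water.

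Iron uptake genes had 14 of 34 members down and 1 up (19 down and 1 up over the list alone), and the call was lost with an estimated correlation (adjusted p = 0.671). The log2 fold change was -1.66 for the outer membrane receptor gene fiu, -1.31 and -1.29 for the enterobactin synthesis genes entA and entB, and -0.92 for the receptor gene fepA. Against the unexposed cultures, 3 iron uptake genes were higher and 5 lower with H2O2, and 17 of 34 were higher with water; the list means were 11.11 with water, 10.64 with H2O2 and 10.72 unexposed. Phosphate starvation genes had 8 of 16 members up and 1 down (8 and 1 over the list alone; adjusted p = 0.393 with an estimated correlation), with the transporter genes pstC at 2.62-fold and pstS at 2.44-fold, and phoH fell by 1.29. Of 21 heat shock genes, 10 rose and 0 fell (11 rose over the list alone; adjusted p = 0.453 with an estimated correlation), among them the protease gene lon (1.62-fold) and the chaperone genes dnaJ (1.43-fold) and dnaK (1.21-fold), while groL stood at a log2 fold change of 0.17 (adjusted p = 0.0554). The rise of dnaK was not called without H2O2 replicate 2 (0.22), without water replicate 3 (0.20) or with only the 6 arrays of the comparison (0.28), and groL was called without water replicate 1 (0.23) or H2O2 replicate 1 (0.20). Against the unexposed cultures the direction turned, with 6 heat shock genes higher and 9 lower with H2O2 (median -0.08), and 14 of 21 lower with water. Of 15 aromatic amino acid genes, 9 rose and 1 fell (9 and 2 over the list alone; adjusted p = 0.731 with an estimated correlation), with tyrA 2.15-fold higher.

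Flagella and chemotaxis had 14 of 28 genes down and 5 up (16 and 7 over the list alone; adjusted p = 0.625 with an estimated correlation), and the master regulator genes flhC and flhD fell, with log2 fold changes of -0.85 and -0.78. Histidine synthesis had 6 of 8 genes down (6 over the list alone; adjusted p = 0.486 with an estimated correlation). Envelope stress had 6 of 14 down and 1 up (6 and 1 over the list alone; adjusted p = 0.463 with an estimated correlation), with the sigma factor gene rpoE at -0.80. Of the 33 lists, these 14 were called with the preset correlation and 4 with an estimated one. Against the unexposed cultures the iron uptake, heat shock, arginine, histidine, phosphate, flagella and envelope lists were not called with the preset correlation (adjusted p = 0.115 to 0.594). Of the 4 lists above, the SOS list was called there with an estimated correlation (adjusted p = 6.14e-10), and the SoxRS (0.0974), pyrimidine (0.103) and nitrogen (0.234) lists were not. The OxyR (16 of 20 genes higher, 0 lower), iron-sulphur (13 of 14, 0 lower) and aromatic (11 of 15, 1 lower) lists were called there with the preset correlation. Their adjusted p-values by camera were 1.61e-06, 1.50e-06 and 3.17e-06, and 0.231, 0.260 and 0.264 with an estimated correlation. Among the genes named by the rule, the largest rises outside the lists were msrQ (7.66-fold) and msrP (7.33-fold), which repair oxidised methionine, the hexuronate genes uxaC (7.18-fold) and uxaA (5.24-fold), and hiuH (5.36-fold). The largest falls among them were those of ddpX (b1488; log2 fold change -3.76), yhdW (-3.06), the asparagine synthetase gene asnA (-2.91) and the cytosine permease gene codB (-2.73), followed by yeaH, caiF, gspC, yfdI, mcrC, ddpA and evgS (-2.72 to -2.36). Part of the fall of yhdW, asnA, yeaH and gspC lay in a high water level, which stood above the unexposed level by 1.835, 1.57, 1.56 and 1.55. For the other genes this difference is not given here.

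**Figure D1:**
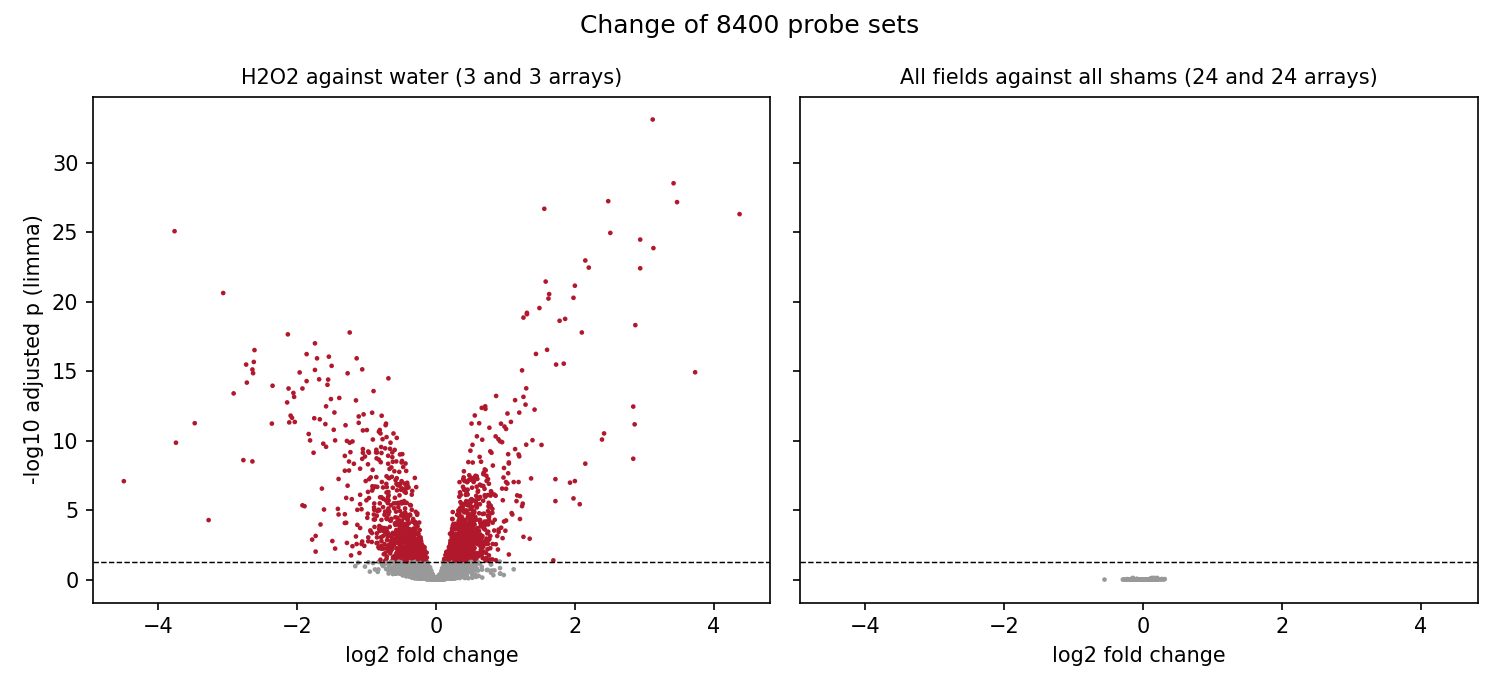
Log2 fold change (x axis) against the negative log10 of the limma adjusted p (y axis) for 8400 probe sets, with H2O2 against water on the left and the average of the 8 field conditions against their shams on the right, on the same axes. Red points passed an adjusted p of 0.05 (dashed line): 1755 on the left and 0 on the right, where fold changes ran from -0.55 to 0.31.

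The negative control asked whether the 2 chambers differed with the fields switched off. No probe set differed between left and right (0 of 8400 by limma, 169 at an unadjusted p under 0.05, where 420 are due to chance alone; the authors' p-values gave 204 as deposited and 0 after adjustment, and limma with array weights 200). The smallest p among genes higher on the left was that of the small RNA gcvB, at a log2 difference of 0.41 (SE 0.15; adjusted p = 0.997), and among genes lower there that of eutB, at -0.20 (SE 0.06). The sugar transport genes mglA and malK stood 1.09 (SE 0.95) and 1.00 (SE 0.93) higher, within the spread between replicates. Of the 33 gene lists, 6 were called between the chambers by camera with the preset correlation, 3 up and 3 down, and 0 with an estimated correlation (adjusted p = 0.939) or by fry. For 96.4% of the 4145 genes the 95% interval of the difference lay within a 2-fold change.

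The field comparisons asked whether a magnetic field changed any transcript. No probe set passed the test in any of the 8 field and sham comparisons (0 of 8400 each by limma, and 0 from the authors' p-values after adjustment). With array weights limma called 0 to 1617 probe sets per comparison, and 11 of 20 exchanges of field and sham labels gave as many calls in sum. Over the 8 comparisons the log2 fold change of katG ran from -0.09 to 0.11, that of recA from -0.09 to 0.05, that of sulA from -0.04 to 0.08, that of dnaK from -0.03 to 0.11 and that of soxS from -0.21 to 0.18. Those of dps, grxA and sufA ran from -0.16 to 0.19, from -0.14 to 0.07 and from -0.15 to 0.18. Larger differences that were not called also occurred. For the power line field at 8 min 18 probe sets differed at least 2-fold, with log2 fold changes from -2.13 to 1.26 over all probe sets. There were 4 for the continuous sinusoidal field at 8 min (-1.28 to 1.60) and 0 or 1 in the other field comparisons. Of the 144 genes that H2O2 changed at least 2-fold, 0 reached a 2-fold difference in 7 of the field comparisons and 1 did in the power line comparison at 8 min.

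For the continuous sinusoidal field, 122, 97 and 99 probe sets had an unadjusted p under 0.05 at 8 min, 2.5 h and 15 h, fewer than the 420 due to chance. The smallest p values belonged to ydcR at 8 min (0.18, SE 0.06), hprS at 2.5 h (-0.44, SE 0.15) and ybcF at 15 h (0.23, SE 0.08), none with an adjusted p below 0.998. For the intermittent sinusoidal field there were 201 at 2.5 h and 455 at 15 h. The electron transfer flavoprotein gene fixB stood at -0.45 (SE 0.12) at 2.5 h. At 15 h the prophage genes yfjI and yfjP stood at -0.41 (SE 0.10; adjusted p = 0.318) and -0.37 (SE 0.10; adjusted p = 0.504), and yiaN at 0.55 (SE 0.16). Without field replicate 3 of that comparison 116 probe sets were called, yfjI (-0.53), yfjP (-0.54) and yiaN (0.75) among them, and the field arrays left, replicates 1 and 2, were among the 4 arrays with the lowest means. For the power line field there were 290, 117 and 73 at 8 min, 2.5 h and 15 h, led by mhpD (0.34, SE 0.10), yahH (-0.36, SE 0.12) and yggF (0.19, SE 0.07). Counts this far below 420, here and between the chambers, mean that the p-values were not evenly spread, as 420 assumes. The reason was not tested, and the low counts are no evidence against a field effect.

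Averaged over all 8 conditions (24 field and 24 sham arrays), 0 probe sets changed by limma and 398 had an unadjusted p under 0.05. The interval of katG was -0.08 to 0.06, that of recA -0.05 to 0.03, that of sulA -0.04 to 0.08, that of ahpC -0.03 to 0.04 and that of rpoS, the general stress sigma factor gene, -0.03 to 0.04. The smallest p among genes was that of yjbF, at 0.11 (SE 0.03; adjusted p = 0.923). The 95% interval lay within a 2-fold change for 99.98% of the genes and within a 1.5-fold change for 99.7%; in the single comparisons the latter ran from 89.4% to 92.6%. Averages by waveform called 0 probe sets for the continuous sinusoidal (180 unadjusted), intermittent sinusoidal (419) and power line (113) fields, and averages by time 0 at 8 min (289), 2.5 h (131) and 15 h (358). The intermittent sinusoidal average called 32 without replicate 3. The field effect differed between the 8 conditions for 0 probe sets (57 at an unadjusted p under 0.05). Array weights, whose estimate did not converge, gave 119 over all conditions, where exchanges of field and sham labels gave up to 1125. They gave 0 to 608 by waveform, 5 to 462 by time and 731 for the difference between conditions. Known changes were added to the real arrays at 200 probe sets at once, 50 at each of 4 folds (1.5, 2, 3 and 4), equal on all arrays of a group. Of those of 1.5-fold 74% to 86% were recovered in the 8 comparisons, and of those of 2-fold 90% to 96%. Recovery of fewer changes, or of changes that vary between arrays, was not measured and may be lower.

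Among gene lists, 51 of 264 pairs of list and field comparison were called by camera with the preset correlation, 32 up and 19 down, and 0 with a correlation estimated from the arrays (smallest adjusted p = 0.995) or by fry. Between the unexposed chambers, with no field, the preset correlation called 6 of 33. Several lists had calls in both directions. The maltose and galactose uptake list was called up in 3 comparisons and down in 1, with malK at 0.87 (SE 0.93) for the continuous sinusoidal field at 8 min and at -0.96 (SE 0.93) for the intermittent sinusoidal field at 2.5 h. The glutamate-dependent acid resistance list was called up in 2 and down in 3, with the activator gene gadE at -0.53 (SE 0.39) and 0.68 (SE 0.39) in those 2 comparisons. The SOS and SoxRS lists were called in 0 field comparisons. The OxyR list was called up in 2 (medians 0.06 and 0.05, intermittent sinusoidal field at 2.5 h and 15 h) and down in 0, and iron uptake and flagella and chemotaxis each up in 3 and down in 0. Averaged over all conditions, iron uptake (median 0.05) and flagella and chemotaxis (median 0.01) were called up with the preset correlation, and neither with an estimated one (adjusted p = 0.998).

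**Figure D2:**
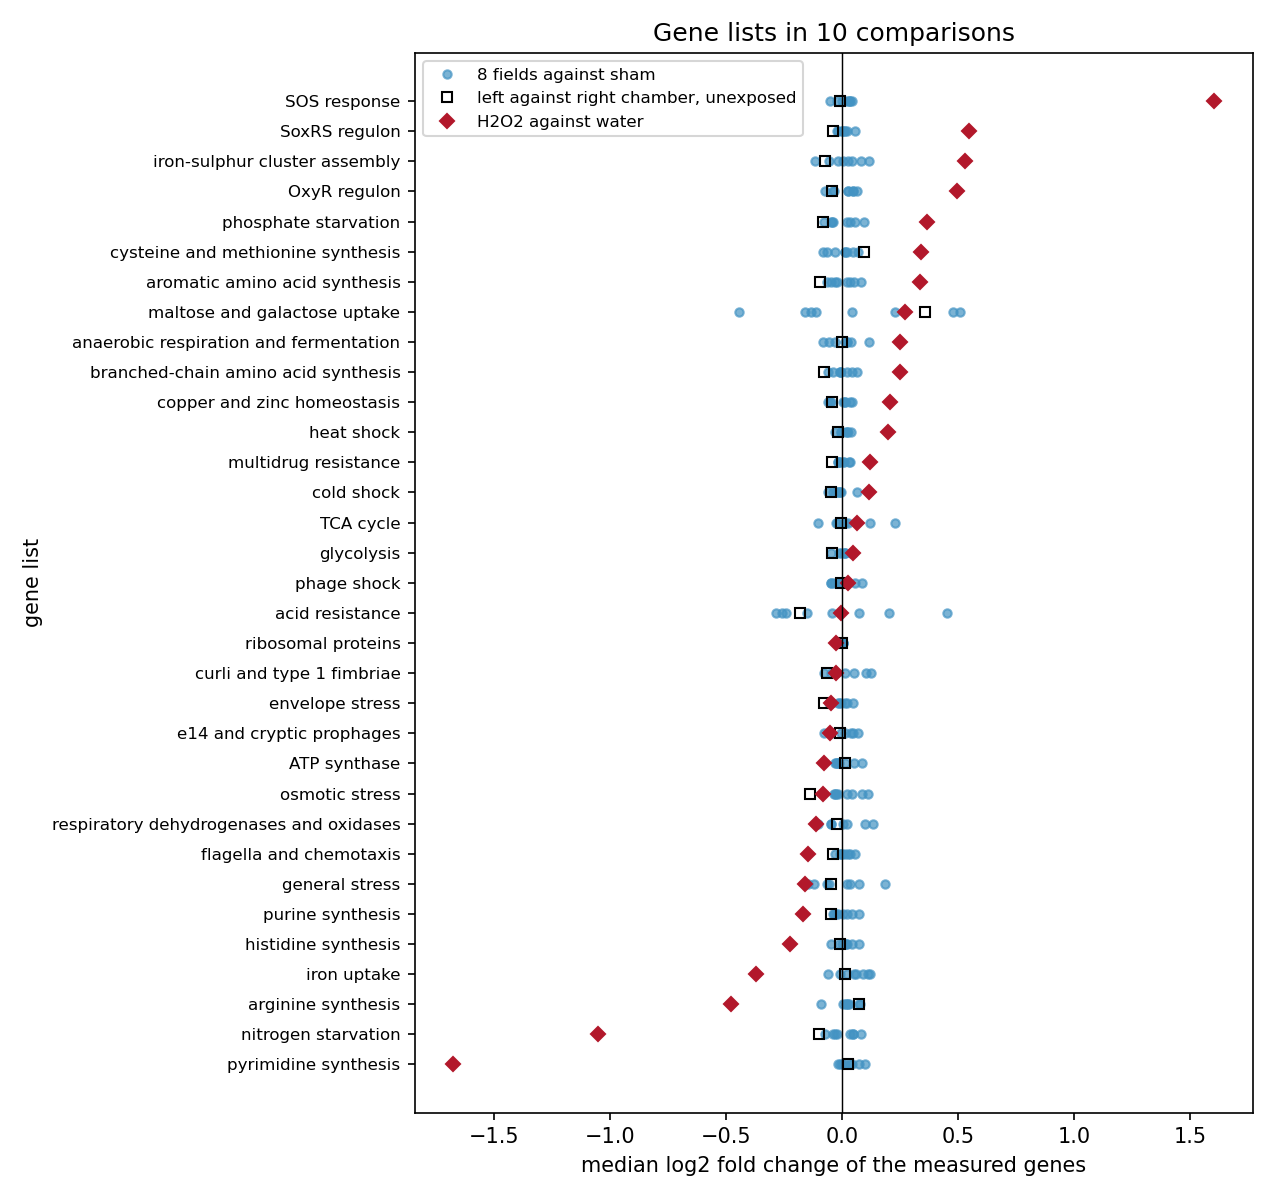
Median log2 fold change (x axis) of each of the 33 gene lists (y axis) for H2O2 against water (red diamonds), the 8 field and sham comparisons (blue circles) and the left against the right unexposed chamber (open squares). The SOS list stands at 1.60 and the pyrimidine list at -1.68 with H2O2, and the widest spread of the field comparisons is in the maltose and galactose uptake list, from -0.45 to 0.51.

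The field profiles were compared with each other and with both controls. Across genes, which are not independent replicates, the mean Pearson r over the 28 pairs of field comparisons was -0.02, with 12 pairs above 0 and a range of -0.69 to 0.61; the mean was 0.04 to 0.06 when a replicate number was left out. In 100 exchanges of field and sham labels the mean r ran from -0.09 to 0.47. The r of the field profiles with the H2O2 profile ran from -0.08 to 0.12 over all genes. Over the 144 genes that H2O2 changed at least 2-fold it ran from -0.28 (power line, 15 h) to 0.29 (power line, 8 min). From 34.7% to 56.25% of these genes had the same sign as with H2O2. The r with the chamber difference ran from -0.64 to 0.59, with 4 of the 8 field comparisons above 0, and 46 of 100 exchanges gave an absolute r as large.

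The 8 sham groups, which received no field, differed from each other at 1084 probe sets (565 genes; F-test in limma), with 2590 at an unadjusted p under 0.05. The maltose regulon gene malM was lowest in the continuous sinusoidal sham at 8 min (9.91 ± 1.33, SD, n = 3) and highest in the intermittent sinusoidal sham at 2.5 h (12.62 ± 0.19), and glnK ran the other way (11.23 ± 0.43 and 9.19 ± 0.17). An F-test between series at fixed time called 537 probe sets and one between times within a series 58, both over all 24 sham arrays, with 1741 and 1661 at an unadjusted p under 0.05. The contrast of 15 h with 8 min over the continuous sinusoidal and power line shams together called 857. The count between all sham groups depended on the replicates: it was 140 without replicate 1, 35 without replicate 2 and 344 without replicate 3. It was higher with array weights (6402, and 4694 gene by gene) and without the arrays of low mean.

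**Figure D3:**
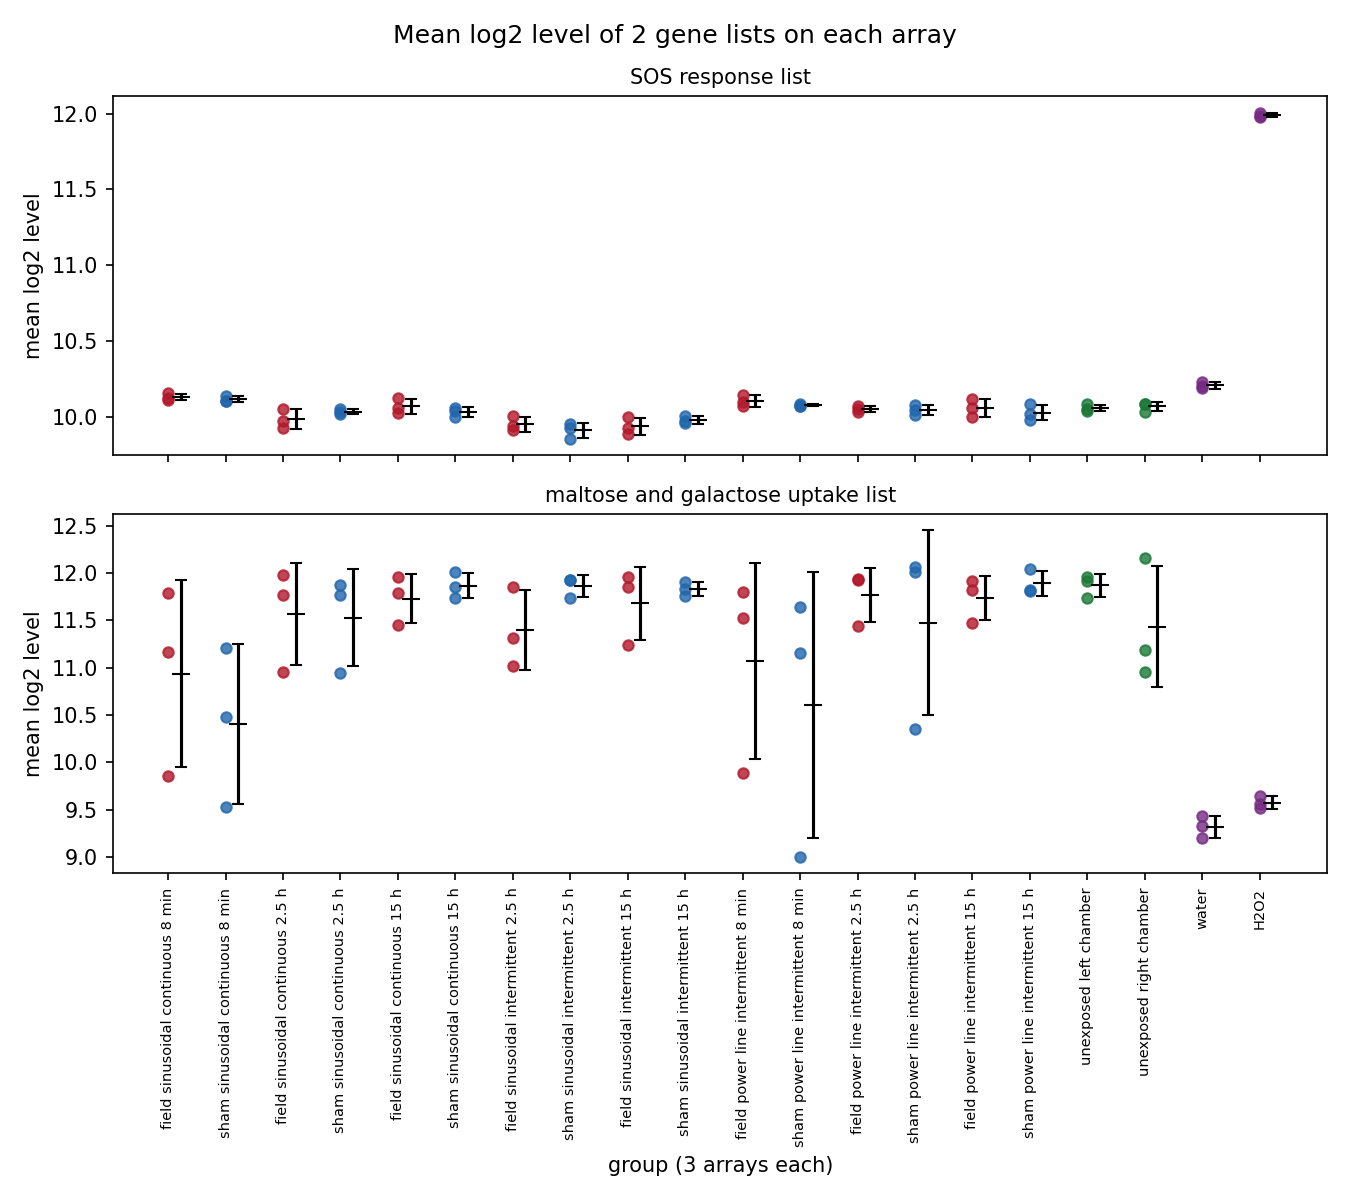
Mean log2 level (y axis) of the SOS list (top) and the maltose and galactose uptake list (bottom) on each array by group (x axis); points are arrays, black bars the mean and SD of 3 arrays, and red, blue, green and purple mark field, sham, unexposed and response control groups. The SOS list stands apart in the H2O2 cultures (11.99 ± 0.01), and the sugar list is low in the water (9.32 ± 0.12) and H2O2 (9.57 ± 0.07) cultures and spreads widely at 8 min in the shams (10.40 ± 0.84 and 10.60 ± 1.41) and the fields (10.93 ± 0.99 and 11.07 ± 1.03).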

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

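The comparisons with the unexposed cultures, the tests of exposure series and sampling time among the shams, the tests of how list calls arise, and the splits for the field comparisons, their averages and the correlation were chosen after the result was seen. Outlying samples within a group were not tested, since the groups hold 3 arrays. Across all 60 arrays, 4 had a mean over 3 MADs below the median and 7 a wide relative log spread, which were the 3 H2O2 arrays, 2 water arrays and 2 field arrays of the intermittent sinusoidal series at 15 h. A control probe set of the array, CreX, which is outside the genes tested, was higher in field than in sham arrays by 0.11 on the log2 scale (SE 0.03; 5.15 against 5.04; adjusted p = 0.0394 over 65 controls) and by 0.19 at 15 h (SE 0.05; 5.18 against 4.99; adjusted p = 0.0263). The field mean was above the sham mean in 6 of the 8 conditions and in the 3 at 15 h, and 17 contrasts were tested, over which the p-values were not adjusted.

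Sugar uptake genes were lower in the response control than in the unexposed cultures: with water all 18 list members were lower, by a median of -2.21 on the log2 scale (adjusted p = 0.263 with an estimated correlation), and with H2O2 15 were lower and 1 higher (adjusted p = 0.561 with an estimated correlation). A loss of array signal common to genes at these levels is argued against, since 10000 random lists matched on level had medians of -0.04 to 0.17 over their central 95%, with -0.61 as the lowest. Random lists hold unrelated genes, so their medians may vary less than those of genes that move together. Control probe sets of the array differed by -1.42 to 0.43 between water and unexposed arrays, so other differences between these arrays are not excluded. A separate culture run or array batch cannot be told apart from the response control itself, because no unexposed array is known to share its run. The water and H2O2 differences from the unexposed cultures correlated at 0.70, which decides nothing, since both subtract the same 6 arrays. Whether they share a culture state with the early sham samples stays open as well. The unexposed minus water profile correlated with the sham 15 h minus 8 min profile at 0.892. In 1 of 100 draws with times exchanged, the real one, r was as large. The other draws ran from -0.891 to 0.885, so that the measure is close to saturated.

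The sham groups differed at 1084 probe sets, and 1 of 100 regroupings of the sham arrays, the real one, gave as many. The highest other gave 633, so chance is argued against if the arrays are independent. The labels do not say whether arrays of a group were separate cultures, so differences between single cultures are not excluded. Differences between exposure series are a candidate source, since an F-test of series at fixed time called 537 probe sets, against 58 for time within series with as many contrasts (5) over the same 24 arrays, though the counts at an unadjusted p under 0.05 were close (1741 and 1661). A joint contrast of the intermittent sinusoidal shams with the other series called 669 probe sets at 2.5 h and 9 at 15 h. The continuous sinusoidal and power line shams differed from each other at 1 or 0. That comparison held fewer arrays, so its called counts are not on equal terms with those of the joint contrast. At an unadjusted p under 0.05 the joint contrast had 1979 probe sets at 2.5 h and 791 at 15 h. The comparison of continuous sinusoidal and power line shams had 1007 and 479. Sampling time is also a candidate source, since 15 h and 8 min differed at 857 probe sets over the continuous sinusoidal and power line series together. This count was reached in 1 of 100 draws with times exchanged, the real one, with 287 as the highest other. Whether series were grown or hybridised on separate days is not given, so no biological explanation of the series differences was tested.

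Gene lists were called in opposite directions in different field comparisons. Exchanging field and sham labels gave as many calls as the 51 observed in 79 of 100 draws, the real one included, with up to 88, so chance cannot be excluded. Members that vary together from culture to culture are a possible explanation, since 0 calls were left with the correlation estimated from the arrays. Whether a sugar uptake state of each culture contributes stays open: 26 calls were left with the list mean as covariate, and all 100 draws, the real one included, left as many or more. The draws with exchanged labels left 32 to 68, so the real count lay below each of them.

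For the counts of changed probe sets, splits of 3 arrays against 3 number 10, too few for a share under 0.05. For H2O2 the real split called 1755 and the highest other 83, and 1 split reached the real count. For its gene lists the real split called 14 and the highest other 15, and 3 splits reached 14. For the left and right chamber and the 8 field comparisons the real count was 0, which all 10 splits reach; the highest others were 0 for the chambers and for the continuous sinusoidal field at 8 min and 2.5 h, 1 at 15 h, 2 and 89 for the intermittent sinusoidal field at 2.5 h and 15 h, and 240, 1 and 6 for the power line field at 8 min, 2.5 h and 15 h. For the 7 averages over conditions and the difference between conditions, all 100 draws reached the count of 0, the real labels included. The highest others were 1 over all conditions, and 2, 167 and 132 for the continuous sinusoidal, intermittent sinusoidal and power line fields. They were 483, 3 and 318 at 8 min, 2.5 h and 15 h, and 131 for the difference of the field effect. The splits with 89 to 483 calls, each the highest of its draws, against a real count of 0, may point to a structure of the arrays. Highest counts picked from draws do not test for one, and its nature was not tested. The mean r of -0.02 between field profiles was reached in 49 of 100 exchanges, with 0.47 as the highest.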

How the results depend on the processing

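The array weights estimated gene by gene, the sugar list covariate and the set without arrays of low mean were added after the data had been seen. For H2O2 against water the count of 1755 stayed within 1332 to 2046 under the replicate block (1804), the low-level filter, quantile normalization, array weights, trended robust eBayes, leaving out a replicate (1332 to 1600), the covariate and without arrays of low mean. It was 822 with only the 6 arrays of the comparison, which estimate the spread from fewer samples, 891 with the authors' deposited p after Benjamini-Hochberg over fewer probe sets, and 194 at a change of at least 2-fold. Median centring moved nothing, since all medians were equal.

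The counts of 0 in the chamber and field comparisons stayed at 0 under the replicate block, the filter, quantile normalization, trended robust eBayes, the 6-array model, the 2-fold threshold, the authors' p after adjustment, the covariate and without the arrays of low mean. Leaving out replicates gave 0 to 116 for the intermittent sinusoidal field at 15 h, 0 to 32 for its average over times, and 0 for the other chamber and field counts. The authors' deposited p as given at 0.05, without adjustment, counted 204 for the chambers, 87, 155 and 84 for the continuous sinusoidal field at 8 min, 2.5 h and 15 h, 236 and 33 for the intermittent sinusoidal field at 2.5 h and 15 h, and 199, 72 and 34 for the power line field at 8 min, 2.5 h and 15 h.

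Array weights, whose estimate did not converge and ran from 0.221 to 14.2, gave 200 for the chambers, 1617 and 6 for the continuous sinusoidal field at 8 min and 2.5 h, 1 for the intermittent sinusoidal field at 2.5 h, 102, 34 and 1473 for the power line field at 8 min, 2.5 h and 15 h, 119 over all conditions, 21 and 608 for the continuous sinusoidal and power line averages, 462, 5 and 7 at 8 min, 2.5 h and 15 h, 731 for the difference between conditions and 6402 for the sham groups. With field and sham labels exchanged at random the same weighting called 893 to 7967 probe sets summed over the 8 comparisons in 20 draws, against 3233 with the real labels, which 11 draws reached, so these calls do not separate field from sham. Weights estimated gene by gene gave 1 for the chambers, 51 for the continuous sinusoidal field at 8 min, 67 for the power line field at 15 h, 1 over all conditions, 1 for the difference between conditions and 4694 for the sham groups.

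The sham count of 1084 was 1162 with the replicate block, 35 to 344 without a replicate number, which leaves 2 arrays per group, and 1754 without the arrays of low mean, none of which is a sham array, so that only the shared estimate of the spread changed. The called gene lists were 4 for H2O2 and 0 for the fields with an estimated correlation, against 14 and 51; fry gave 19 and 0, and the covariate left 26 for the fields; the cause was not tested. The replicate block gave 12 and 54. The numbers were not taken to pair the arrays (r of same-numbered arrays -0.63 to 0.65, and 10 of 30 correlated best with their own number), and the block moved no count by over 1.5 times. Of the values of named genes under alternatives, 16 with H2O2 lost their call and 2 gained one, 6 in the other comparisons gained one, and 0 reversed; leaving out H2O2 replicate 2 ended the calls of soxS (0.54), dnaK (0.22), sufS (0.51), entD (-0.79), hisH (-0.22) and rybB (-0.94), water replicate 2 those of hisH (-0.19) and rybB, water replicate 3 those of dnaK (0.20), hisH, rybB (-0.96) and rpoS (0.16), and the 6-array model those of argB, hisH, dnaK and rpoS. The 6 gains were in the intermittent sinusoidal comparison at 15 h without field replicate 3. Signal over background is not given in these files, so low levels could not be set apart by detection.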

Other observations

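The contrasts between sham times and with the unexposed cultures, and the genes named for them, were chosen after the data had been seen. In the continuous sinusoidal and power line series together, the sham cultures differed between 8 min and 15 h at 857 probe sets (419 higher and 438 lower at 15 h), with 21 and 4 in each series alone. The tryptophanase gene tnaA was 6.36-fold higher at 15 h, the maltose transporter gene malK 5.90-fold, the galactose transporter gene mglA 5.54-fold and the acetate permease gene actP 4.46-fold, and 16 of 18 maltose and galactose uptake genes rose and 0 fell (adjusted p = 0.452 with an estimated correlation). Of 21 heat shock genes 15 rose and 0 fell, by a list median of 0.23, and this list kept its call with an estimated correlation (adjusted p = 0.0275). Iron uptake genes had 18 of 34 members lower and 0 higher (adjusted p = 0.584 with an estimated correlation). The nitrogen genes glnK, nac and amtB stood at -1.63, -1.18 and -1.16, while 6 of the 14 genes of their list were lower and 0 higher, with a median of -0.02, and the list was not called (adjusted p = 0.0581, and 0.584 with an estimated correlation). Between 2.5 h and 15 h 0 probe sets differed by limma, with 255 at an unadjusted p under 0.05.

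The water arrays differed from the 6 unexposed ones at 1984 probe sets, 1201 higher and 783 lower. The log2 difference was -4.76 for the galactose transporter gene mglA, -4.07 for tnaA, -3.86 for the glycerol phosphate transporter gene glpT and -3.64 for the ribose transporter gene rbsA, and 14 of 17 genes of the tricarboxylic acid cycle were lower and 0 higher (adjusted p = 0.0766 with an estimated correlation). The nitrogen list had 9 of 14 genes higher and 0 lower (adjusted p = 0.0523 with an estimated correlation), and its mean level was 11.76 ± 0.24 with water (n = 3 arrays), 10.30 ± 0.24 with H2O2 (n = 3) and 10.81 ± 0.08 on the unexposed arrays (n = 6). So glnK, at 12.98 with water, stood at 9.23 with H2O2 and 10.07 unexposed, and with H2O2 the difference from the unexposed level was -1.12 for nac (adjusted p = 0.00110), -0.84 for glnK (0.0463) and -0.20 for amtB (0.622). Of the nitrogen list 9 of 14 genes were lower with H2O2 than unexposed and 0 higher (median -0.66; adjusted p = 0.234 with an estimated correlation). The pyrimidine gene pyrB, in contrast, was at 14.25 both with water and unexposed and at 12.39 with H2O2, and recA at 12.88, 12.87 and 14.45.

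With H2O2, the other 19 lists were not called by camera with the preset correlation. Their genes called up and down were 1 and 6 of 14 for purine synthesis, 6 and 1 of 14 for branched-chain amino acid synthesis, 7 and 2 of 26 for anaerobic respiration and fermentation, 4 and 0 of 10 for multidrug resistance, 12 and 4 of 24 for cysteine and methionine synthesis, 1 and 6 of 54 for ribosomal proteins, 0 and 3 of 20 for respiratory dehydrogenases and oxidases, 0 and 4 of 14 for osmotic stress, and 1 and 3 of 18 for general stress. They were 1 and 3 of 15 for curli and type 1 fimbriae, 2 and 0 of 18 for maltose and galactose uptake, 1 and 3 of 26 for prophage genes, 0 and 0 of 9 for ATP synthase, 2 and 4 of 11 for copper and zinc homeostasis, 0 and 0 of 11 for acid resistance, 3 and 0 of 17 for the tricarboxylic acid cycle, 2 and 2 of 10 for cold shock, 0 and 2 of 7 for phage shock, and 1 and 2 of 14 for glycolysis. For copper and zinc (median 0.21, mean -0.16), phage shock (0.02 and -0.04) and glycolysis (0.05, with a mean above 0) the test's direction was down, against the sign of the median.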
